A study of Mus musculus with 4 samples.

How the data were processed

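Total RNA from mouse footpads of postnatal day 3 was hybridised to 4 Agilent 2-colour oligonucleotide arrays with probes of 60 bases. Per the labels, 2 arrays carried wild-type RNA and 2 carried Tabby RNA, all of the C57BL/6 strain. The footpad RNA was labelled with Cy3 on each array. A common reference, labelled with Cy5, was hybridised with it. Per the labels' protocols, the reference was an equal pool of RNA from 11 mouse cell lines mixed at 2 parts to 1 part with RNA from mouse embryonic stem cells, and 2.5 ug of the mixture was labelled. Both RNAs were amplified and labelled with a linear amplification kit for small RNA amounts. The dye orientation was the same on all 4 arrays, so a constant dye effect cancels in the difference between groups.

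The submitters' processing notes name Agilent Feature Extraction, and the version was 9.5.1.1 per the file headers. The deposited scanner files give, per the file headers, the mean intensity and the median local background of each spot in each channel, with no normalization. The same files hold processed intensities, which Feature Extraction had background-subtracted with spatial detrending, set to surrogate values where signals were low, and dye-normalized within the array, per the file headers. They also hold the log10 ratio of reference over footpad signal, per the file headers, and flags for spots that were well above background, saturated or outlying. A deposited value table holds the authors' processed values on a log10 scale for 25164 probes. Its construction was worked out from the values. Each entry equals the log10 processed footpad signal minus the log10 processed reference signal plus the mean over the 4 arrays of the log10 processed reference signal, with a largest difference of 0.000159. Scale, centring and direction of the table are therefore known, and its columns have medians of 2.58 for wild type 1, 2.58 for wild type 2, 2.58 for Tabby 1 and 2.58 for Tabby 2. The rule by which the authors chose its probes is not given in the sources used here.

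Each array held 43451 spots, of which 1417 were controls and 42034 were other spots for 42006 distinct probes. The name fields of the files repeat the probe ID for all of these probes and list their position as unmapped, so 0 probes could be paired with a gene. Results are therefore given by probe ID and probe sequence, with no chromosome position. The 25 gene lists and the individual genes fixed before the data were examined could not be matched to probes, and their tests were not run. The gene affected in Tabby was not examined for the same reason.

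The intensities were corrected for background with the normexp method at an offset of 50 and normalized within each array by loess with a span of 0.3, in R 4.3.3 with limma 3.58.1. Control spots and spots with an outlier flag had weight 0 in the loess fit. The offset compresses the fold changes of dim probes. Spots of one probe were averaged. A probe was tested if it was free of outlier flags on each array and well above background in the footpad channel on at least 2 of the 4 arrays. The effect is the mean log2 ratio of footpad over reference in Tabby minus that in wild type. It was tested with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. A probe that was not well above background on any array of a group has only a bound there. Its fold is given as at least the ratio of the brighter group's mean footpad signal to a floor. The floor is the mean, over the arrays of the dimmer group, of the lowest signal among probes well above background or the probe's own signal, whichever was higher, after loess and Aquantile scaling. A dye effect that is constant over the arrays cancels in such a bound, while one that differs between arrays would not, and no dye swap was made to measure it.

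Nothing in the labels says whether the replicates of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. All 4 arrays lay on 1 slide with 1 scan time. Wild type 1 and 2 took positions 1 and 2, and Tabby 1 and 2 took positions 3 and 4, so position on the slide and group cannot be told apart. Per the labels, wild-type footpads were from males and Tabby footpads from mice of mixed sex, so sex and genotype are not separated either.

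The test, the alternatives and the rule for named items were set before the data were examined. That rule took the largest increases and decreases among genes past the threshold in which both arrays of one group lay on the same side of both arrays of the other. Without gene names it was applied to probes and limited to 2 probes per direction. Alternatives covered the background correction, the normalization, the source of the ratios, the channels used, the filter on dim probes, spots with an outlier flag, the variance model, array weights, a fold threshold, the replicate number as a block and leaving out each array in turn. Removal of the GC trend, the test of the reference channel, the classes of footpad over reference signal, the overlap of 25 bases and the comparison of hexamers were chosen after seeing the data. Array weights used statmod 1.5.0, and files were read with the data.table package, version 1.17.8.

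The pipeline was tested on simulated data for 28545 probes in which 50 probes were changed at each of 4 fold sizes. It recovered 2% of the probes changed 1.25-fold, 42% at 1.5-fold, 84% at 2-fold and 96% at 4-fold. Of 114 calls in the simulation, 2 were unchanged probes, and 0 had the wrong sign. Noise was simulated in the footpad channel alone. It was drawn independently for each spot from the variance model of the main fit, around a mean signal common to all arrays. The simulation therefore holds no trend that follows the groups, and its share of false calls does not carry over to the real arrays. The number of arrays limits the precision of each value.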

Results

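Gene expression in mouse footpads was measured at postnatal day 3 in wild-type and Tabby mice, with 2 samples in each group. The footpad is the skin site where mice form sweat glands. Tabby mice carry a defect in Eda, the X-linked gene of the signalling ligand ectodysplasin, and form no sweat glands there. Per the series' design, the comparison was made to find genes that depend on Eda while sweat glands develop. Other ages in that design were not analysed here. Each footpad sample was read against a common reference RNA on its own array.

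The arrays were of similar brightness. The median footpad signal was 113.4 and 120.6 intensity units in wild type 1 and 2, and 134.5 and 115.4 in Tabby 1 and 2. The median reference signal was 167.5, 163.5, 161.9 and 166.1 in the same order. Footpad signal was well above background at 67.2% and 67.6% of spots in wild type and at 68.1% and 67.5% in Tabby. On each array 0 spots were saturated. Of the distinct probes, 28545 were tested, 13445 were too dim and 16 had an outlier flag. Log2 ratios of the 2 wild-type arrays correlated across probes at r = 0.996, and those of the 2 Tabby arrays at r = 0.994. The SD of the log2 difference was 0.11 between the wild-type arrays and 0.14 between the Tabby arrays. Between a Tabby and a wild-type array it ranged from 0.19 to 0.22.

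Larger changes in Tabby footpads were mostly decreases. Among probes past the threshold, 50 were at least 2-fold lower in Tabby and 3 were at least 2-fold higher. At 4-fold or more, 14 probes were lower and 1 was higher. At 8-fold or more, 7 were lower and 1 was higher. The 2 probes with the largest decreases were 36.9-fold and 31.1-fold lower at the offset used, which compresses folds, and the probe with the largest increase was at least 39.1-fold higher. With median centring in place of loess, 36 probes were called at least 2-fold lower and 7 at least 2-fold higher, and with Feature Extraction ratios 13 were lower and 1 was higher. Such calls numbered 44 lower and 2 higher without wild type 1, 59 and 9 without wild type 2, 47 and 9 without Tabby 1, and 57 and 8 without Tabby 2.

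In all, 539 of 28545 probes (1.89%) passed the threshold by limma's moderated test, of which 376 were lower and 163 were higher (30.2%) in Tabby. Most of these changes were small, with 382 calls (70.9%) under 1.5-fold. At 1.5-fold or more, 129 probes were lower and 28 were higher. The median absolute log2 change was 0.45 among the called probes and 0.093 among all tested probes. An unadjusted p under 0.05 was found for 7311 probes (25.6%), where chance would give 1427. Both arrays of one group lay on the same side of both arrays of the other at 57.8% of tested probes, where chance would give 33.3%. Across tested probes, which are not independent replicates, the log2 change correlated with the GC content of the probe at rho = 0.24, and after removal of that trend 258 probes were called lower and 114 higher. With median centring, which put the median log2 change of all tested probes at 0.084 in place of 0.00070, the split over all calls turned around, to 142 lower and 272 higher. At 1.5-fold or more it was then 92 lower and 72 higher. That fit gave the probe with the largest decrease a limma adjusted p of 7.15e-239. With 2 arrays per group, such a value arises only where nearly the same variance is assumed for all probes. Calls then follow the size of the change and hardly the spread of each probe. The median of 0.084 thus favours increases, and the 2 splits are not like for like. Calls at 1.5-fold or more numbered 67 lower and 3 higher without wild type 1, 109 and 15 without wild type 2, 131 and 53 without Tabby 1, and 192 and 61 without Tabby 2. The count of calls depended on single arrays, with 70 calls (4.29% higher) without wild type 1, 124 (12.1%) without wild type 2, 348 (37.1%) without Tabby 1 and 1795 (35.8%) without Tabby 2, and other processing moved it between 14 with Feature Extraction ratios and 1064 with an intensity trend and robust prior.

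**Figure D1:**
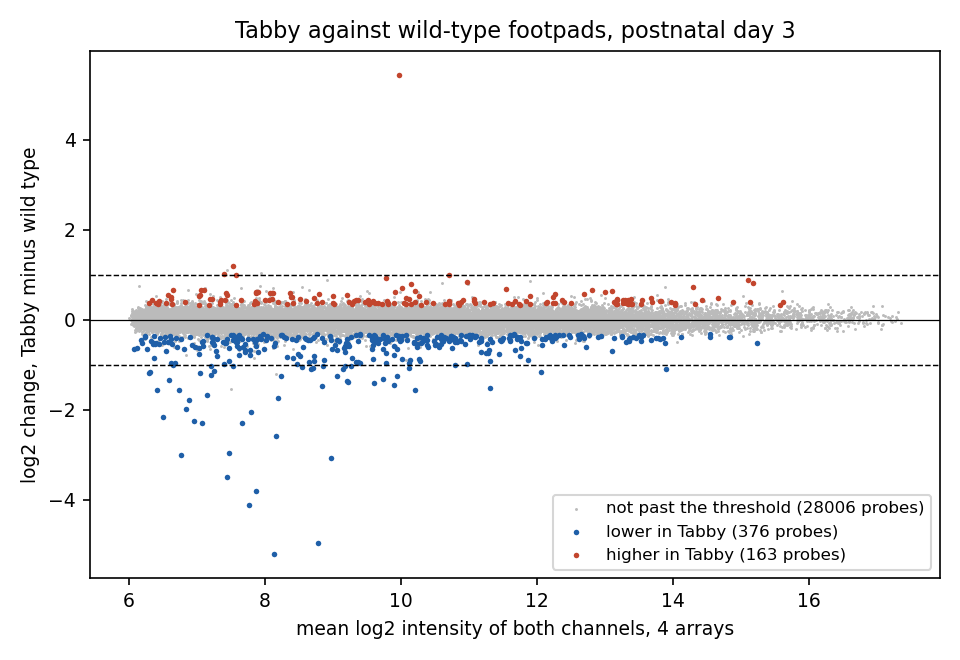
Log2 change of each tested probe, Tabby minus wild type, against its mean log2 intensity over both channels and 4 arrays. Blue points are the 376 probes called lower, red points the 163 called higher, grey points the rest, and dashed lines mark 2-fold, beyond which 50 called probes lie below and 3 above.

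Probe Z00025964-1, of sequence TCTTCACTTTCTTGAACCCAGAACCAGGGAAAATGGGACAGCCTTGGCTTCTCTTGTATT, had the largest decrease. Its mean log2 ratio of footpad over reference was 5.22 ± 0.099 (SD, n = 2) in wild type and 0.017 ± 0.23 (SD, n = 2) in Tabby. The log2 change was -5.21 with an SE of 0.11 and a limma adjusted p of 3.87e-05. Its mean log2 footpad signal was 12.43 in wild type and 6.46 in Tabby. Of the 2 Tabby arrays, 1 measured it well above background. Its reference signal also differed between the groups, by -0.77 on the log2 scale. The size of its change depended on the processing, with a log2 change of -5.98 with Feature Extraction ratios and -8.16 in the footpad channel alone. Its adjusted p was 0.135 with Feature Extraction ratios and 0.103 in the authors' value table, and at most 0.0339 under the other alternatives that tested it, which leaves out detection on all 4 arrays.

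Probe Z00047655-1, of sequence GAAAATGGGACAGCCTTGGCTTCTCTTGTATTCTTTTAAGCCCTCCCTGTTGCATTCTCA, overlaps the sequence of Z00025964-1 by 32 bases. Its mean log2 ratio was 4.79 ± 0.11 (SD, n = 2) in wild type and -0.17 ± 0.027 (SD, n = 2) in Tabby. The log2 change was -4.96 with an SE of 0.070 and a limma adjusted p of 1.07e-05. It was well above background on all 4 arrays. Its reference signal differed between the groups by -0.054 on the log2 scale. Its log2 change was -5.38 with Feature Extraction ratios and -5.65 in the footpad channel alone.

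Probe Z00016441-1, of sequence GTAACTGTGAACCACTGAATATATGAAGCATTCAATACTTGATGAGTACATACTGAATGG, had the largest increase. It was well above background on both Tabby arrays and not well above background on either wild-type array. Footpad signal was at least 39.1-fold higher in Tabby, with mean log2 signals of 11.71 in Tabby and 6.42 in wild type and a limma adjusted p of 1.68e-05. The mean log2 ratio was 0.91 ± 0.080 (SD, n = 2) in Tabby and -4.54 ± 0.19 (SD, n = 2) in wild type. Its reference signal differed between the groups by -0.16 on the log2 scale. With Feature Extraction ratios the fitted log2 change was larger, 9.12, with an adjusted p of 0.129. In the authors' value table it was 9.12 with an adjusted p of 0.0979, and in the footpad channel alone 9.01 with 0.0757. These fitted values are no measured folds, since the wild-type signal was not well above background. The adjusted p was at most 0.0187 under the other alternatives that tested the probe, which leaves out detection on all 4 arrays. The labels give the wild-type mice as male and the Tabby mice as mixed sex, and whether this transcript differs between the sexes was not examined.

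Probe Z00017323-1, of sequence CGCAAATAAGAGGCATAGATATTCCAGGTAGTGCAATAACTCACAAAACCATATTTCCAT, had the next largest increase. It too was well above background on both Tabby arrays and on neither wild-type array. Footpad signal was at least 2.27-fold higher in Tabby, with mean log2 signals of 7.44 in Tabby and 6.26 in wild type and a limma adjusted p of 0.00328. The mean log2 ratio was -0.75 ± 0.11 (SD, n = 2) in Tabby and -1.95 ± 0.090 (SD, n = 2) in wild type. The fitted log2 change was 1.20 with the offset of 50, 2.84 with offset 0, 3.81 with Feature Extraction ratios and in the authors' value table, and 3.91 in the footpad channel alone, none of them a measured fold. This probe and Z00016441-1 share no stretch of more than 5 bases.

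**Figure D2:**
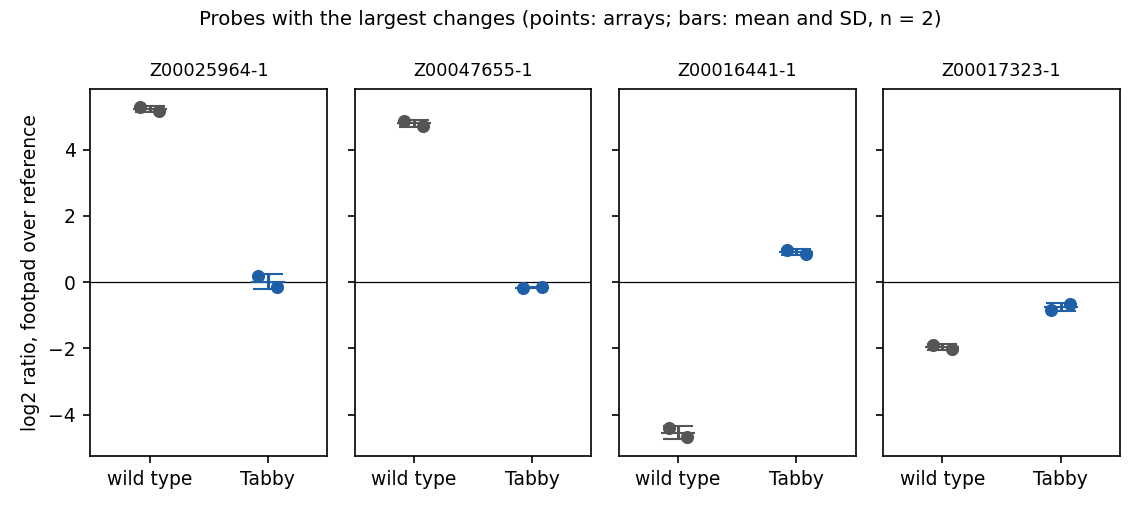
Log2 ratio of footpad over reference for the 2 probes with the largest decrease and the 2 with the largest increase. Points are single arrays and bars give the mean and SD of 2 arrays per group; the wild-type and Tabby arrays lie apart for each probe, with wild-type means of 5.22, 4.79, -4.54 and -1.95 from left to right.

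Some probes crossed the detection limit between the groups. On both wild-type arrays and neither Tabby array, 124 tested probes were well above background. Of these, 12 were called lower in Tabby and 0 were called higher. Their footpad signals were lower in Tabby by bounds that ranged from at least 1.40-fold to at least 5.77-fold, and 6 of the 12 bounds were 2-fold or more. On both Tabby arrays and neither wild-type array, 170 tested probes were well above background. Of these, 3 were called higher and 0 were called lower, with bounds of at least 1.23-fold, at least 2.27-fold and at least 39.1-fold. Detection in 1 group alone chose these probes, which largely fixes the direction of their calls, so the counts of 0 carry no support. Among all tested probes 1.89% were called.

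Probes that overlap in sequence had similar log2 changes. There were 800 pairs of tested probes that shared at least 25 bases, with 1436 probes among them. In 27 pairs at least 1 probe was called, and in each of the 27 the other probe's log2 change had the same sign. In 16 pairs both probes were called, 15 of them lower and 1 higher, and in 5 pairs both were called at 2-fold or more. Across the 800 pairs the log2 changes correlated at r = 0.959 and rho = 0.874. Without the pair of largest change r was 0.921, and for 800 random pairs it was -0.0014. The median absolute difference within a pair was 0.037 on the log2 scale. Pairs are not independent replicates, since both probes of a pair read the same RNA samples.

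**Figure D3:**
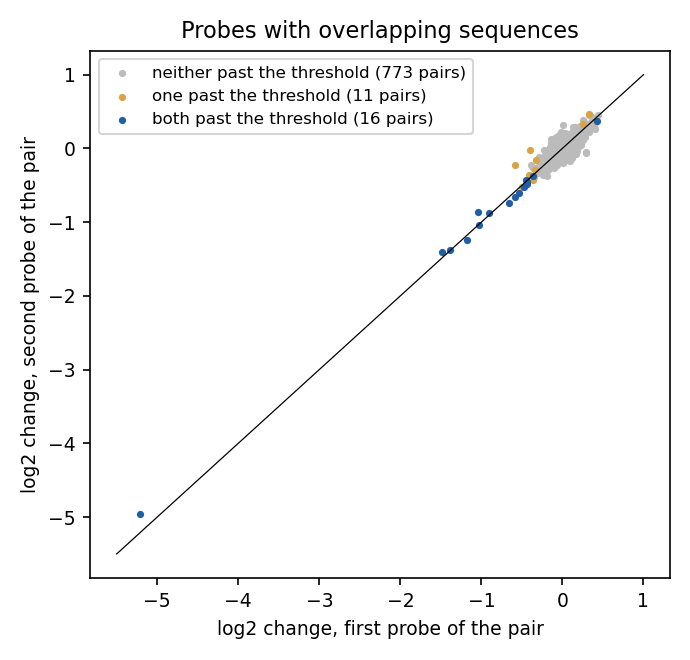
Log2 change, Tabby minus wild type, of the first against the second probe of each of 800 pairs that share at least 25 bases, with the line of equal change. Blue points are the 16 pairs with both probes called, orange points the 11 pairs with 1 probe called and grey points the other 773; the correlation across pairs was 0.959.

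Decreases of at least 1.5-fold were more frequent among probes with footpad signal far above or far below the reference signal. Of 2093 probes with footpad signal at least 4-fold above the reference over the 4 arrays, 37 (1.77%) were called at least 1.5-fold lower in Tabby. Of 750 probes with footpad signal at least 4-fold below the reference, 9 (1.20%) were. Of the 25702 probes within 4-fold, 83 (0.323%) were. By Fisher's exact test, two-sided and adjusted over 3 comparisons, the class above the reference differed from the class within 4-fold at p = 1.53e-13, and the class below differed from it at p = 0.00181. A difference between the classes above and below was not detected, at an adjusted p of 0.398. Increases of at least 1.5-fold were called for 7 probes (0.334%) above the reference, 2 (0.267%) below and 19 (0.0739%) within 4-fold. By the same test, increases in the class above differed from those within 4-fold at an adjusted p of 0.00749, and those in the class below did not pass, at 0.178. The Tabby arrays help to set these classes, so a change can itself move a probe between them. With classes set by the wild-type arrays alone or the Tabby arrays alone, the adjusted p for decreases was 1.38e-24 or 0.000768 in the class above and 0.0248 or 0.000768 in the class below. The odds ratio for decreases was 8.68 or 2.57 in the class above and 2.83 or 3.86 in the class below, so its size depended on which arrays set the class. The arrays that set a class still enter the change, so these checks do not remove the dependence. For increases in the class above it was 0.437 or 0.000268, so that call depended on which arrays set the class. Probes of overlapping sequence or of one transcript are not independent, so these p-values are too small. The offset of 50 also draws the ratios of dim probes toward 0, which tends to keep them within 4-fold and under 1.5-fold alike. The classes were not compared at equal brightness, so the higher shares in the outer classes cannot be told apart from this effect.

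Probes that hold the hexamer AATAAA, the most common polyadenylation signal of mammalian transcripts, lay slightly lower in Tabby. The median log2 change of the 2177 such probes lay 0.091 below that of the other probes, and their shift was -0.069 at equal GC content. Equal GC content here means the shift within each of 5 GC classes, averaged with weights by the number of probes that hold the hexamer. The lowest class spanned 16.7% to 36.7% GC, so GC content was matched only roughly. In each of the 4 comparisons of a Tabby with a wild-type array the shift at equal GC content was below 0, from -0.044 to -0.10. These comparisons reuse the same 4 arrays and are not independent of each other. Between replicates the shift was 0.017 in wild type and 0.043 in Tabby, the latter close in size to the smallest shift between the groups. Of the probes with AATAAA, 2.80% were called lower and 0.184% higher, and of the 26368 probes without it, 1.19% and 0.603%. With median centring, where calls follow the size of the change as said above, these shares were 0.689% lower and 0.367% higher with AATAAA, and 0.482% and 1.00% without it. After the GC trend was removed, 1.19% of the probes with AATAAA were called lower and 0.880% of those without it. The excess of lower calls was not stable when single arrays were left out. The shift, not matched for GC, stayed below 0 then, from -0.071 without Tabby 1 to -0.12 without Tabby 2. The shares are not matched for GC content, and the differences between them were not tested.

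**Figure D4:**
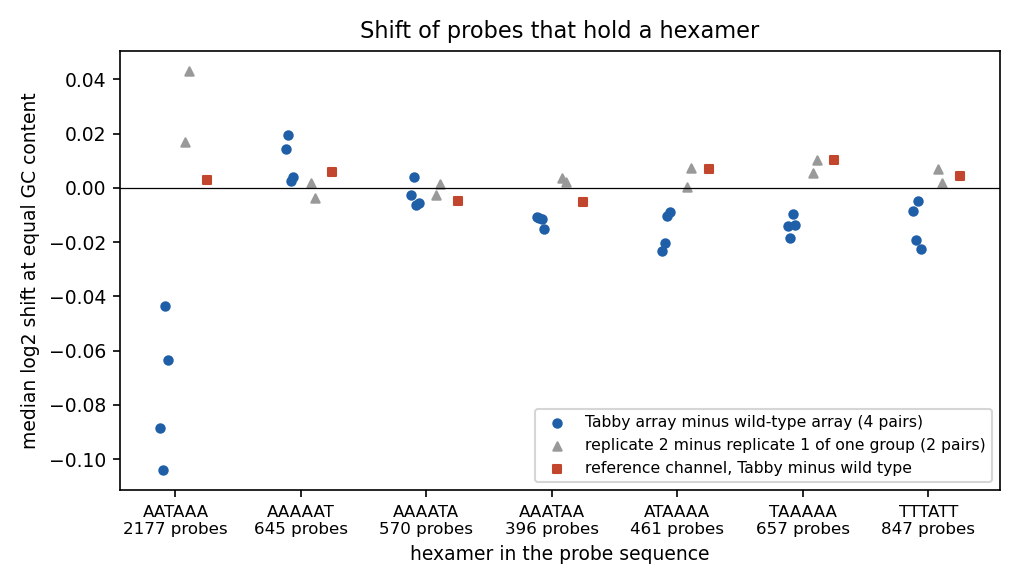
Median log2 shift, at equal GC content, of probes that hold each of 7 hexamers against probes that do not. Blue points are the 4 comparisons of a Tabby with a wild-type array, grey triangles the 2 comparisons of replicates and red squares the reference channel; for AATAAA the blue points lie between -0.044 and -0.10 and the red square at 0.0029.

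The authors' value table holds part of the tested probes. Of 17819 tested probes in it, 372 (2.09%) were called, and of 10726 tested probes outside it, 167 (1.56%) were. The odds ratio was 1.35, with p = 0.00141 by Fisher's exact test, two-sided. Probes of overlapping sequence or of one transcript are not independent, so this p-value is too small. Probes in and outside the table were not compared at equal brightness, and the rule that chose them is not known. Of the probes called at 2-fold or more, 36 were in the table and 17 were outside it, among them Z00047655-1.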

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

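Tests chosen after the result they bear on was seen were those of the reference channel, the GC trend, the splits of the arrays, AATAAA at equal GC content, labelled transcript ends and female transcripts; the tests on other A-rich hexamers and on failed spots were set before their results were seen.

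The reference channel holds the same RNA mixture on each array and is not itself part of the comparison, yet 3 probes passed the threshold there between Tabby and wild-type arrays, with log2 changes of -4.58, -2.74 and 3.68. At the same probes the log2 ratio of footpad over reference changed by 0.048, -1.01 and 0.046 in the main fit. The second of these is among the 50 probes called at least 2-fold lower. The reference changes came from the processed signals of that channel alone, scaled to the 75th percentile with no offset. Detection in the reference channel was not asked for. These changes and those of the ratios are therefore on unlike scales, and the footpad change cannot be worked out from them.

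More probes differed between the groups than chance would give, with 7311 at an unadjusted p under 0.05. Tested alone on processed signals, the footpad channel gave 5096 such probes and the reference channel 1728. This argues against slide position or hybridisation acting alike on both channels as the whole cause, although the noise of the 2 channels was not compared. An effect equal in both channels would also cancel in the ratios that gave the 7311 probes. After the GC trend was removed 7024 such probes were left, so that trend is not the whole cause either. In the reference channel the change between the groups also followed GC content, at rho = 0.12 against 0.28 in the footpad channel. The reference RNA is the same on each array, so some technical difference between the arrays did follow the groups. Of the 3 ways to split the 4 arrays into 2 and 2, only 1, the real one, gave as many as 539 calls. The others gave 0 each, with 195 and 516 probes at an unadjusted p under 0.05 by limma, fewer than the 1427 of chance. In those splits any difference that follows the real groups counts as spread within a group, which lowers the number of calls. They therefore cannot show what chance would give, and 3 splits are too few for a share under 0.05. Genotype, sex, position on the slide acting on the Cy3 channel, and the handling of the footpad RNA follow the groups and stay open. So does a difference between the animals sampled, if the replicates of a group did not come from separate animals.

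Probes that hold AATAAA lay lower in Tabby; this was 1 of 5 sequence motifs looked at, after the GC trend had been seen. Their shift of -0.091 was -0.069 at equal GC content, which argues against GC content as the whole cause, as far as 5 broad classes can match it. In the reference channel these probes shifted by 0.0029 where in the footpad channel they shifted by -0.089, which argues against hybridisation acting on both channels. The other 5 arrangements of the same bases had a median shift of -0.0092, so A-rich sequence in general does not account for it. A candidate explanation is fewer labelled transcript ends near the poly(A) site in the Tabby samples: the reverse complement TTTATT shifted by -0.016 against -0.069 for AATAAA, and the median log2 change, not matched for GC, was -0.023 where AATAAA began within the first 15 bases of the probe and -0.098 where it began at bases 46 to 55. The position values had been seen before this explanation was written down, and a difference in RNA quality or amplification and a biological difference in the choice of polyadenylation sites both remain open.

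Probe Z00016441-1 was well above background on both Tabby arrays and on neither wild-type array. Its reference signal was not lower on the wild-type arrays, with a log2 difference of -0.16 for Tabby minus wild type, where failed spots would have lowered it there too; this argues against failed spots on the wild-type arrays. The probe could belong to a transcript of female cells, since the labels give wild type as male and Tabby as mixed sex; the bound of at least 39.1-fold does not separate this from an effect of genotype, and the 2 cannot be told apart while the transcript has no name here.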

How the results depend on the processing

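Removal of the GC trend and classes of footpad over reference signal set by 1 group alone were chosen after seeing the data. Of the 4 comparisons of such a class with probes within 4-fold, 3 kept their side of the threshold under both; increases in the class above had an odds ratio of 4.54 over all arrays and 1.64 with wild type alone. Both groups' arrays lay apart at each of the 539 called probes, so leaving out an array, a block, array weights, another variance model or Aquantile scaling could not turn a sign. Of the alternatives that recompute the ratios, 539 kept their sign with no background subtraction, with median centring and with the GC trend removed, 538 with offset 0, 536 with Feature Extraction ratios and 537 with the footpad channel alone. Of 372 tested in the authors' value table, 370 did. The count of calls was not stable. It was 22 with offset 0, 14 with Feature Extraction ratios, 14 in the authors' value table, 42 with the footpad channel alone, 335 with no filter on dim probes, 1064 with an intensity trend and robust prior and 157 with at least 1.5-fold asked for as well, where the added condition itself removes calls. For the others the cause was not tested. Without 1 array, whose lone partner is then assumed to vary like the other group, it ranged from 70 without wild type 1 to 1795 without Tabby 2. With a replicate block it was 103. Same-numbered arrays deviated from their group means with r = -0.068, so no effect shared by replicate number was seen. That value cannot tell whether the samples were collected or handled in pairs. Counts were within 1.5 times of 539 with no background subtraction, median centring (414, of which 65.7% were higher and 228 were among the 539), Aquantile scaling, which leaves the ratios as they are, detection on all 4 arrays, spots with an outlier flag kept, array weights, and the GC trend removed (372, of which 358 were among the 539). The count with median centring came from nearly the same variance for all probes, so its closeness to 539 does not show that the count is stable.

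The 53 probes called at 2-fold or more kept their sign under these recomputed ratios, with 36 tested in the authors' value table. Still called were 20 with offset 0, 12 with Feature Extraction ratios, 10 of 36 in the authors' value table and 25 with the footpad channel alone. Called also without each of the 4 arrays in turn were 63 probes, 61 of them lower. Not run were the alternatives that need gene names, which are 1 probe per gene, the mean of a gene's probes, the gene lists and the named genes, nor a slide or scan block, since there was 1 slide and 1 scan. The shift of AATAAA probes, examined after seeing the data, stayed below 0 under each alternative run, from -0.13 with the footpad channel alone to -0.062 with the GC trend removed. Weak signal left 13445 probes untested.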

Other observations

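Values by GC content of the probe were compared only after the data had been seen. The median log2 change, Tabby minus wild type, was -0.052 in the class of 6338 probes with the lowest GC content and -0.017, 0.011, 0.022 and 0.042 in the next 4 classes. Across probes, rho with GC content was 0.20 to 0.22 in the 4 comparisons of a Tabby with a wild-type array. It was 0.00064 between the wild-type arrays and -0.087 between the Tabby arrays. In the footpad channel alone rho was 0.28, and in the reference channel it was 0.12.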
